A study of Caenorhabditis elegans with 18 samples.

How the data were processed

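RNA was measured in 18 samples of Caenorhabditis elegans N2, the standard laboratory wild-type strain of this nematode. Per the labels' protocols, larvae of the earliest stages were grown in liquid culture to the last larval stage and young adulthood and then placed in wells with 0.3 g of soil that held 2700 mg/kg lead, 4200 mg/kg zinc and 310 mg/kg cadmium. The soil came with or without nanoscale zero-valent iron (nZVI), a reactive iron powder used to immobilise metals. Each well received 7500 to 10000 worms and OP50 bacteria as food, and the exposure lasted 48 h at 20 °C in the dark. Worms were recovered on colloidal silica and filtered to remove young larvae, and RNA was extracted with the RNeasy Mini kit. The labels give 3 sampling times, 0 days, 14 days and 4 months, each with 3 control and 3 nZVI samples. They do not say from what event the times are counted, and the exposure was the same at every time.

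Per the labels' protocols, RNA was labelled with the GeneChip WT PLUS kit and hybridised to the Gene 1.0 ST array made for C. elegans, 1 array per sample. The submitters' processing notes name RMA and the Transcriptome Analysis Console, and their versions are not given in the sources used here. RMA corrects background, normalises quantiles between arrays and summarises probes into probe sets, so the values deposited by the authors are log2 signals per probe set that were already normalised, and a change shared by most genes would not appear in them. The table holds 28387 probe sets in 18 columns, each matched to its sample by name. Of the probe sets, 25546 were paired with a single gene symbol in the platform annotation, 646 with several and 2195 with none. Symbols were updated through the Entrez identifier, which matched 25495 of them, and named 25478 genes, 57 of them through more than 1 probe set. Only probe sets with a single symbol are named, and probe sets of closely related family members may cross-hybridise.

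Each comparison was fitted with limma (lmFit, contrasts.fit and eBayes with default settings) on the deposited log2 values, with 1 coefficient per group over all 18 arrays, so that every comparison shared a single estimate of spread. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 28387 probe sets, and a probe set was called at an adjusted p under 0.05. The 11 comparisons were nZVI against control soil at each time and averaged over times, the 3 differences of the nZVI effect between times, and 14 days or 4 months against 0 days within each soil. The comparisons of both later times with 0 days use the same 0-day arrays, so their overlaps are not compared. The design, the gene lists, the rule for naming genes and all alternatives except those named as added were fixed before the data were examined. The number of arrays, 3 per group, limits the precision of every value. The labels number the replicates and the series text speaks of independent RNA, but neither says that they came from separate cultures. The p-values therefore weigh each difference against a spread between these arrays that may be technical only.

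The 42 gene lists covered metal handling, stress responses, detoxification, immunity, reproduction, development, cuticle, metabolism, protein turnover and tissue markers, with 1 probe set per gene, the one with the highest mean signal. Gene classes were the 173 letter prefixes of C. elegans symbols with at least 10 measured genes. Both were tested with camera at its preset correlation of 0.01 and Benjamini-Hochberg adjustment within a comparison, again with a correlation estimated from the data, and with fry. Counts of called members are given over all probe sets and adjusted over the list alone. The rule for named genes took, among called probe sets with a single symbol whose 3 and 3 values did not overlap, the 12 largest rises and the 12 largest falls for each nZVI comparison at a single time and 6 and 6 for the other comparisons, up to 4 members with the smallest p in each list, and always mtl-1, mtl-2, cdr-1, ftn-1, ftn-2, sod-3 and vit-2.

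The replicate numbers were checked as a pairing through the correlation of same-numbered arrays' deviations from their group means over probe sets. Between nZVI and control soil all 3 pairs exceeded 0.1 only at 4 months (0.104 to 0.374). At 0 days the same correlations ran from 0.0224 to 0.226 and at 14 days from 0.0261 to 0.155. The pairing rests on the replicate numbers in the labels and is uncertain. At 4 months nZVI array 3 correlated at 0.104 with control array 3 and at 0.103 with control array 2. Identical values made up at most 0.109% of any pair of arrays, so no array was taken for a copy of another. The scripts were tested on simulated data with the real spread, for the comparison at 0 days over 28387 probe sets. The fit recovered 16%, 70%, 98% and 100% of 50 probe sets each changed by 0.5, 1, 2 and 3 on the log2 scale. It called 10 of 28157 unchanged ones. Camera found a list of 30 genes shifted by 0.5 and called none of the 42 unchanged lists, as did camera with an estimated correlation. Fry called 1 of the unchanged lists. Genes were drawn independently, so the simulation cannot show how often camera calls unchanged lists when genes vary together.

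The alternatives tried were quantile normalisation again, cyclic loess, median centring, filters on dim probe sets (the lowest 25% or 50% by mean), a variance model with trend and robustness, sample weights, only the compared groups in the fit, only probe sets with 1 gene name, fold thresholds of 2, the replicate number as a block, and leaving out each array in turn. Added after the data were seen were fits without the control arrays 1 and 3 at 4 months, whose values spread less than those of every other array, and a replicate block within each time. Developmental scores were built from the fixed lists as the first principal component of standardised values, over 127 germline, oocyte, cell division and neuropeptide genes (59.6% of their variance, higher where germline genes were higher) and over 18 moulting genes (51.6%). Fits were made in R 4.3.3 with limma 3.58.1, and figures in Python 3.11.15 with matplotlib 3.10.9.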

Results

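Wild-type C. elegans were exposed for 48 h to soil contaminated with lead, zinc and cadmium, without (control soil) or with nanoscale zero-valent iron (nZVI soil), at sampling times of 0 days, 14 days and 4 months, with 3 arrays per group. The 18 arrays had medians between 3.85 and 3.99 on the log2 scale, and arrays of the same group correlated at 0.970 to 0.996. The median standard deviation of a probe set within a group ran from 0.150 (control soil, 14 days) to 0.259 (control soil, 4 months). Control arrays 1 and 3 at 4 months had interquartile ranges of 3.803 and 3.702, and every other array had at least 4.072.

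The largest axis of variation separated the soils as much as the times. The first principal component held 30.2% of the variance, of which time accounted for 41.7% and treatment for 42.4%. The second held 22.1% and followed time (79.2%, treatment 3.60%), and the third held 13.3% (time 18.3%, treatment 30.97%). At 14 days nZVI array 2 lay apart from its group on the first component, at 10.49 against 59.99 and 64.19. The same array had the highest age score in its group, 9.99 against -4.50 and -4.55. This score is the first component of 127 germline, oocyte, cell division and neuropeptide genes.

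**Figure D1:**
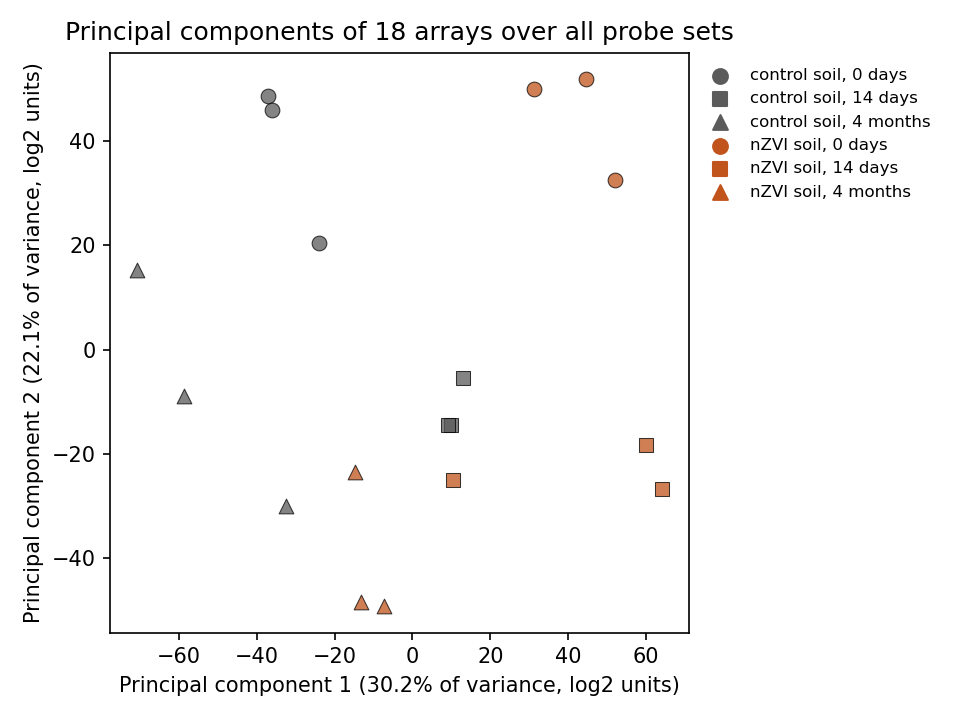
Scores on the first and second principal components (30.2% and 22.1% of the variance, log2 scale), 1 point per array, by soil and sampling time. nZVI array 2 at 14 days lies at 10.49 on the first component and the other nZVI arrays of that time at 59.99 and 64.19.

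At 0 days, worms in nZVI soil carried more transcript of the ferritin genes ftn-1 and ftn-2 and of the iron exporter fpn-1.2 than worms in control soil. Camera called hypoxia genes and those of metal detoxification, heat shock, the oxidant regulator SKN-1 and the germline lower. With an estimated correlation hypoxia alone held (adjusted p = 0.00545, and 0.276, 0.269, 0.0745 and 0.232 for the others). C-type lectins were higher, and so by camera alone were digestive proteases and fasting genes (adjusted p = 0.00473, 0.0562 and 0.0609 with an estimated correlation). Of 28387 probe sets, 2333 rose and 2197 fell (15.96% in total), and 930 and 797 of these changed at least 2-fold. The total called was 4530, and 1827 with a 2-fold change at an unadjusted p under 0.05. It was 2826 without control array 1, 2987 without nZVI array 2 and 2868 without nZVI array 3. With the age score in the fit it was 1482, and 1751 with a score of 18 moulting genes.

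The ferritin gene ftn-1, whose product stores iron, rose at 0 days by 3.07 ± 0.24 (log2 fold change ± SE, 8.42-fold, adjusted p = 2.7e-07), and ftn-2, the more steadily expressed ferritin, by 0.60 ± 0.12 (1.52-fold, adjusted p = 0.00172). The iron exporter fpn-1.2 rose by 2.10 ± 0.22 (adjusted p = 5.9e-06), and the other 2 ferroportin genes were not called. The metal importer smf-2 rose by 2.43 ± 0.41. In the iron and heme list 9 of 23 genes rose, 2 fell and 12 were not called (11 and 4 adjusted over the list alone; camera adjusted p = 0.00492, adjusted p = 0.173 with an estimated correlation).

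In the metal detoxification list 6 of 15 genes fell at 0 days and the other 9 were not called (3 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.0129, adjusted p = 0.276 with an estimated correlation). They included the cadmium-responsive cdr-4 (-1.15 ± 0.13), numr-1 (-1.88 ± 0.29) and numr-2 (-2.96 ± 0.51), and hmt-1 (-1.66 ± 0.19), a transporter of phytochelatins. The metallothioneins, small proteins that bind zinc and cadmium, were not called: mtl-1 at -0.33 ± 0.18 (adjusted p = 0.250) and mtl-2 at 0.39 ± 0.15 (adjusted p = 0.0955). The fall of cdr-1 (-0.60 ± 0.17, adjusted p = 0.0245) was not called without control array 1 (adjusted p = 0.0914), control array 2 (0.0773), nZVI array 2 (0.0540) or nZVI array 3 (0.113). Of 13 SKN-1 and glutathione genes 7 fell and 1 rose (8 and 2 adjusted over the list alone; camera adjusted p = 4.1e-04, adjusted p = 0.0745 with an estimated correlation), among them nit-1 (-1.79 ± 0.17), gst-4 (-1.76 ± 0.26) and gcs-1 (-1.26 ± 0.15), the enzyme that limits glutathione synthesis. Of 15 heat shock genes 6 fell and 3 rose (7 and 3 adjusted over the list alone; camera adjusted p = 0.0154, adjusted p = 0.269 with an estimated correlation), with hsp-16.2 at -1.90 ± 0.28 and hsp-43 at -1.50 ± 0.15. Of 6 hypoxia genes 5 fell (6 adjusted over the list alone), a call that held with an estimated correlation (adjusted p = 0.00545). The sulphide enzyme genes sqrd-1 (-1.99 ± 0.22) and cysl-2 (-1.11) were among them.

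Immune families moved in different directions at 0 days. C-type lectins, many of them secreted by the intestine, rose in 61 of 247 genes and fell in 3 (64 and 4 adjusted over the list alone; camera adjusted p = 7.8e-08, 0.00473 with an estimated correlation), with clec-31 at 2.28 and clec-51 at 1.99. Lysozymes and immune effectors rose in 21 of 58 genes and fell in 5 (23 and 5 adjusted over the list alone; adjusted p = 0.0630 with an estimated correlation), and spp-1 and irg-3 (2.27) rose while irg-2 (-2.11) fell. Antimicrobial peptides fell in 13 of 27 genes and rose in 2 (15 and 2 adjusted over the list alone; adjusted p = 0.0609 with an estimated correlation), with nlp-29 at -2.87 and cnc-4 at -2.14. The pals genes, which respond to intracellular pathogens, fell in 14 of 37 genes and rose in 1 (15 and 1 adjusted over the list alone; adjusted p = 0.232 with an estimated correlation), with pals-3 at -1.57.

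Of 28 digestive proteases 16 rose at 0 days and 12 were not called (18 risen adjusted over the list alone; camera adjusted p = 3.2e-10, adjusted p = 0.0562 with an estimated correlation), including cpr-4 (1.40) and cpr-6 (1.04), proteases of the gut lumen and lysosome. Of 40 fasting and beta-oxidation genes 11 rose and 1 fell (11 and 2 adjusted over the list alone; adjusted p = 0.0609 with an estimated correlation), led by the lysosomal lipases lipl-1 (1.96 ± 0.14), lipl-3 (1.82) and lipl-5 (1.57). Lipid synthesis rose in 8 of 23 genes and fell in 1, the fatty acid synthase fasn-1 (-1.32; adjusted p = 0.209 with an estimated correlation for the list). Vacuolar ATPase genes rose in 11 of 18 and fell in 1, with vha-6 at 1.23, intestine markers in 5 of 8, with ges-1 at 1.40, and muscle genes in 11 of 23, with tnt-4 at 1.36 (12 and 1, 6, and 13 adjusted over the list alone; adjusted p = 0.232, 0.232 and 0.173 with an estimated correlation). Proteasome genes fell in 7 of 33 (11 adjusted over the list alone), with rpn-3 at -0.62 (adjusted p = 0.232 with an estimated correlation). Cytochrome P450 genes rose in 15 of 74 and fell in 5 (19 and 5 adjusted over the list alone), with cyp-34A2 at 3.40. UDP-glucuronosyltransferases rose in 17 of 67 and fell in 6 (23 and 8 adjusted over the list alone), with ugt-28 at -2.11 (adjusted p = 0.232 and 0.430 with an estimated correlation for these 2 lists).

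Camera called the germline, cell division and sperm lists lower in nZVI soil at 0 days, and none of the 3 held with an estimated correlation. Of 27 germline and meiosis genes 14 fell and 13 were not called (25 fallen adjusted over the list alone; camera adjusted p = 3.7e-10, adjusted p = 0.232 with an estimated correlation), with syp-3 at -1.27 and zim-2 at -0.97. Cell division fell in 5 of 31 genes (7 adjusted over the list alone; adjusted p = 0.430 with an estimated correlation), with cye-1 at -0.73, and moulting genes rose in 5 of 18 (7 adjusted over the list alone; adjusted p = 0.430 with an estimated correlation), with mlt-7 at 0.97. The age score was lower by 10.9 in nZVI soil and the moulting score higher by 4.64, that is 2.37 and 2.21 within-group standard deviations. Sperm genes fell in 4 of 57 (3 adjusted over the list alone), with spe-36 at -2.93, and embryo genes rose in 8 of 49 and fell in 3 (11 and 3 adjusted over the list alone), and neither call held with an estimated correlation (adjusted p = 0.527 and 0.430). The sperm call was lost without control array 2 (adjusted p = 0.0755) or nZVI array 3 (0.102), and the embryo call without control array 2 (0.0693), nZVI array 2 (0.0583) or nZVI array 3 (0.239). FMRFamide-like neuropeptides rose in 3 of 31 (8 adjusted over the list alone) and synapse genes in 2 of 15 (3 adjusted over the list alone; adjusted p = 0.430 and 0.527 with an estimated correlation), and the synapse call was lost without control array 2 (0.109). Adult and pre-adult collagens fell in 2 of 8 (3 adjusted over the list alone), col-38 (-2.12) and bli-2 (-1.47), with an adjusted p of 0.173 with an estimated correlation, and the bli-2 call was lost without control array 1 (adjusted p = 0.0626), 2 (0.123) or 3 (0.0833) or nZVI array 2 (0.0933) or 3 (0.141).

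The 12 largest rises at 0 days were scl-11 (6.22 ± 1.00, 74.7-fold), Y59A8B.26 (6.17), spp-11 (5.31), col-108 (5.27), scl-12 (5.22), scl-13 (5.00), T26C12.2 (4.82), fipr-25 (4.72), tyr-3 (4.50), oac-39 (4.33), T05B4.12 (4.26) and F47B8.13 (4.15). The scl genes encode secreted cysteine-rich proteins. The 12 largest falls were C25F9.2 (-4.22), ZC21.10 (-3.86), fipr-22 (-3.69), parg-2 (-3.33), srt-42 (-3.30), T05A8.2 (-3.30), gst-9 (-3.25), F19B10.13 (-3.23), C33A12.19 (-3.16), fbxa-75 (-3.14), F43C1.7 (-3.03) and F17C11.21 (-3.02). parg-2 encodes a glycohydrolase that removes poly(ADP-ribose), a mark of DNA damage. The adjusted p of these 24 genes ran from 3.8e-08 (parg-2) to 0.00127 (T05B4.12).

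Camera called no shift of the other lists at 0 days. Glutathione S-transferases fell in 11 of 48 genes and rose in 3, ABC transporters rose in 11 of 48 and fell in 7 (pgp-14 2.38, haf-7 -1.98), and cuticle collagens fell in 26 of 170 and rose in 9 (sqt-1 -1.57, camera adjusted p = 0.133). Antioxidant enzymes rose in 3 of 28 and fell in 5, with gpx-3 at 1.92. DAF-16 targets rose in 4 of 14, the respiratory chain in 4 of 41 with 3 lower, and zinc transport in 2 of 20 with 2 lower. Oocyte, glycolysis and histone lists each had 2 genes higher and 2 lower, osmotic stress 1 and 2, endoplasmic reticulum stress 2 lower, mitochondrial stress 1 lower and male markers 1 higher. limma called no gene among 5 yolk proteins or 75 ribosomal proteins (0 and 1 at an unadjusted p under 0.05).

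At 14 days the gene list with the most genes higher in nZVI soil was the cuticle collagens, the proteins of the worm's outer skin. SKN-1 and glutathione genes were lower, and metal detoxification genes were called lower by camera alone (adjusted p = 0.00316 and 0.189 with an estimated correlation). The ferritins were not called. The lists of C-type lectins, lysozymes and immune effectors, fasting and beta-oxidation genes and digestive proteases were higher. Of the probe sets 1023 rose and 1529 fell (2552, 8.99% in total), 462 and 748 of them at least 2-fold. Sample weights raised the total to 6846, and a 2-fold change at an unadjusted p gave 1332. Centring the arrays on their medians gave 1299 rises and 1270 falls. The total was 1577 without control array 2 and 1562 without nZVI array 1.

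Of 170 cuticle collagens 94 rose at 14 days and 76 were not called (120 risen adjusted over the list alone; camera adjusted p = 1.6e-38, 0.0147 with an estimated correlation). Among them col-138 rose by 2.49, col-135 by 2.04, col-73 by 1.99 and sqt-1 by 1.65. The adult and pre-adult collagens rose in 7 of 8 genes (8 adjusted over the list alone; adjusted p = 7.1e-04 with an estimated correlation), with the adult-stage col-19 at 2.42 ± 0.29 (5.37-fold), bli-1 at 2.06 and col-7 at 1.40. The age score was higher by 6.72 and the moulting score by 2.34, but these hung on single arrays. Without nZVI array 2 they were 1.89 and 4.798, and the moulting difference was 1.28 and 0.93 without nZVI arrays 1 and 3.

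SKN-1 and glutathione genes fell at 14 days in 8 of 13 (10 adjusted over the list alone), and the call held with an estimated correlation (adjusted p = 0.00316), with gst-4 at -1.61, nit-1 at -1.24 and gcs-1 at -1.15. Glutathione S-transferases fell in 16 of 48 (18 lower and 1 higher adjusted over the list alone; adjusted p = 0.0202 with an estimated correlation), with gst-9 at -1.81 and gst-16 at -1.56. In the metal detoxification list 5 of 15 fell and 2 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.00130, adjusted p = 0.189 with an estimated correlation). numr-2 fell by 3.11, hmt-1 by 1.69 and cdr-4 by 1.64, while cdr-1 rose by 1.01 ± 0.17 (adjusted p = 9.1e-04). mtl-2 rose by 0.59 ± 0.15 (adjusted p = 0.0204), a call lost without control array 2 (adjusted p = 0.0965), control array 3 (0.0633), nZVI array 1 (0.0903) or nZVI array 2 (0.0535), and mtl-1 was not called (adjusted p = 0.913). Heat shock genes fell in 4 of 15 (4 lower and 1 higher adjusted over the list alone; adjusted p = 0.260 with an estimated correlation), with hsp-16.2 at -1.74, and the list was not called without nZVI array 2 (adjusted p = 0.109).

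The iron exporter fpn-1.2 rose by 2.03 at 14 days, with ftn-1 at 0.28 (adjusted p = 0.593) and ftn-2 at -0.12 (adjusted p = 0.641). In the iron and heme list 5 of 23 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0117, adjusted p = 0.189 with an estimated correlation), including the heme-responsive hrg-11.4 (1.49) and hrg-11.2 (1.37). sod-3 (adjusted p = 0.758) and vit-2 (0.67, adjusted p = 0.0645) were not called.

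At 14 days C-type lectins rose in 48 of 247 and fell in 4 (59 and 5 adjusted over the list alone), with clec-66 at 2.07. Lysozymes and immune effectors rose in 18 of 58 and fell in 4 (23 and 5 adjusted over the list alone), with irg-6 at 3.32 and irg-2 at -2.47. Digestive proteases rose in 17 of 28 (20 adjusted over the list alone), with asp-16 at 2.19. Fasting genes rose in 13 of 40 and fell in 1 (16 and 1 adjusted over the list alone), with lipl-1 at 1.90 and lipl-5 at 1.63. These 4 lists held with an estimated correlation (adjusted p = 7.1e-04, 0.0114, 0.0114 and 7.1e-04). Antimicrobial peptides fell in 7 of 27 and rose in 1 (11 and 3 adjusted over the list alone; cnc-6 -1.68), pals genes fell in 7 of 37 (12 adjusted over the list alone; pals-4 -1.57) and FMRFamide-like neuropeptides in 5 of 31 (5 adjusted over the list alone; flp-11 -0.92), with adjusted p of 0.167, 0.191 and 0.400 with an estimated correlation. DAF-16 targets rose in 3 of 14 (4 adjusted over the list alone; lys-7 1.22) and yolk proteins, which feed the oocytes, in 2 of 5 (5 adjusted over the list alone; vit-6 1.29). Oocyte genes rose in 3 of 38 (3 adjusted over the list alone), with cpg-22 at 1.33, a call lost without nZVI array 1 (adjusted p = 0.0607) or 3 (0.0531). With an estimated correlation these 3 lists had adjusted p of 0.189, 0.191 and 0.231.

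Smaller shifts called by camera at 14 days did not hold with an estimated correlation. Lipid synthesis rose in 6 of 23 and fell in 2 (10 and 3 adjusted over the list alone; adjusted p = 0.280 with an estimated correlation), with fasn-1 at -1.29, and was not called without nZVI array 1 (adjusted p = 0.0530). Muscle genes rose in 4 of 23 (8 higher and 1 lower adjusted over the list alone; 0.392), with tnt-2 at 0.88, and respiratory chain genes in 2 of 41 (0.189). Glycolysis (pyk-2 0.66; 0.361) and vacuolar ATPase (vha-6 0.89; 0.392) each had 1 gene higher, and their calls were lost without control array 3 (adjusted p = 0.130) and nZVI array 1 (0.0680) respectively. Cell division was higher (0.587) and synapse lower (0.479) with no gene called by limma (8 of 31 and 3 of 15 at an unadjusted p under 0.05). The cell division call was lost without control array 3 (adjusted p = 0.156) or nZVI array 2 (0.741), and the synapse call without nZVI array 2 (0.271). The remaining lists were not called: cytochrome P450 (10 up, 6 down), UDP-glucuronosyltransferases (6, 8), ABC transporters (5, 9), histones (0, 3), antioxidant enzymes (0, 3), intestine (3, 0), sperm (0, 2), endoplasmic reticulum stress (0, 2), embryo (2, 2), osmotic stress (1, 1), hypoxia (0, 1), male markers (0, 1), zinc transport (1, 0) and moulting (1, 0). limma called no gene in the mitochondrial stress, germline, ribosomal or proteasome lists (1, 0, 2 and 3 at an unadjusted p under 0.05).

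The 12 largest rises at 14 days were irg-6 (3.32 ± 0.22, 9.96-fold), E01G4.6 (3.10), F47B8.13 (3.06), col-108 (2.94), Y105C5B.15 (2.72), T22F3.11 (2.65), vap-2 (2.60), col-138 (2.49), col-38 (2.45), znf-782 (2.43), col-19 (2.42) and bli-2 (2.42). The 12 largest falls were C25F9.2 (-4.58), parg-2 (-3.55), K02F3.13 (-3.42), T05A8.2 (-3.30), C14F11.11 (-3.14), numr-2 (-3.11), Y42A5A.11 (-3.07), F43C1.7 (-3.07), R11D1.14 (-2.95), fbxa-50 (-2.92), T04C12.23 (-2.92) and pgp-6 (-2.88), an ABC transporter. The adjusted p of these 24 genes ran from 2.6e-08 (parg-2) to 0.0135 (znf-782). The znf-782 call was lost without control array 3 (adjusted p = 0.0558), nZVI array 1 (0.0833) or nZVI array 3 (0.0800).

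**Figure D2:**
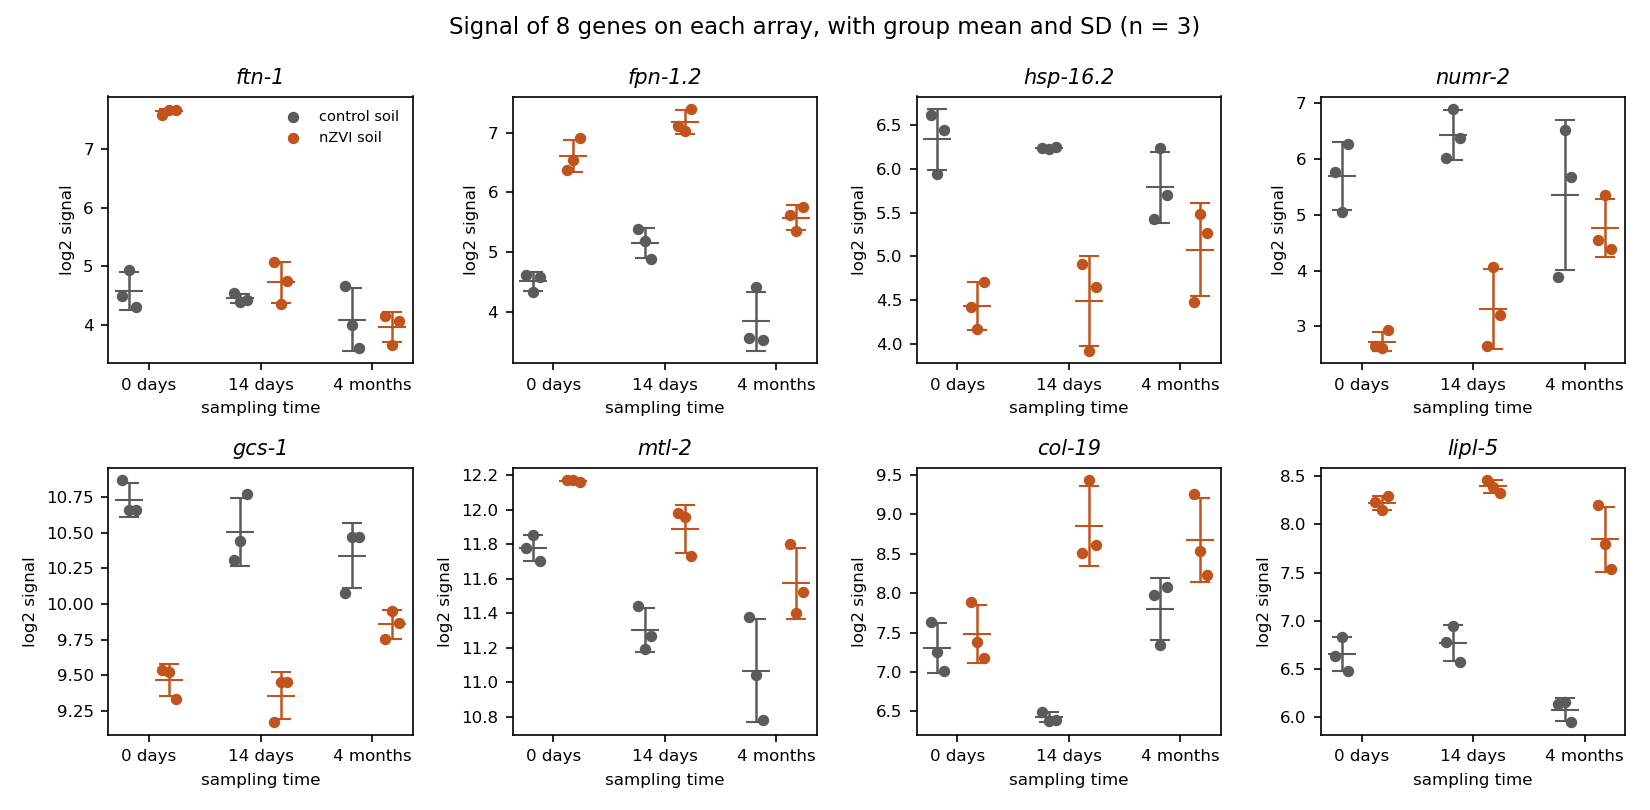
Log2 signal of ftn-1, fpn-1.2, hsp-16.2, numr-2, gcs-1, mtl-2, col-19 and lipl-5 in control and nZVI soil at each sampling time, 1 point per array with mean and SD (n = 3). ftn-1 was higher in nZVI soil at 0 days (log2 fold change 3.07) and not called at 14 days and 4 months, and lipl-5 was higher at each time (1.57, 1.63 and 1.77).

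At 4 months the adult and pre-adult collagen, digestive protease and fasting lists were higher in nZVI soil, and more genes rose than fell. Glutathione S-transferases were called lower by camera alone (adjusted p = 0.109 with an estimated correlation), and the metal detoxification list was not called. The control arrays of this time varied the most of the 6 groups. Of the probe sets 1355 rose and 654 fell (2009, 7.08% in total), 689 and 247 of them at least 2-fold. The total was 3394 with sample weights, 382 with only the compared groups in the fit and 1292 for a 2-fold change at an unadjusted p. The total hung on single arrays: 970 without control array 1, 5415 without control array 2, 773 without control array 3, 1004 without nZVI array 2 and 983 without nZVI array 3. Without the narrow control arrays 1 and 3, a fit added after the data were seen, it was 186. With the interquartile range of each array in the fit it was 156, and 972 with the moulting score. With the replicate number as a block it was 2057, and 2573 with a block within each time, which was also added.

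Adult and pre-adult collagens, fasting genes and digestive proteases held with an estimated correlation at 4 months. Adult and pre-adult collagens rose in 5 of 8 genes (7 adjusted over the list alone; adjusted p = 0.00309 with an estimated correlation), with bli-1 at 2.91 and bli-2 at 2.77. The adult-stage col-19 (0.87, adjusted p = 0.0759), col-7 (0.26, adjusted p = 0.499) and col-62 (adjusted p = 0.118) were not called. Fasting and beta-oxidation genes rose in 11 of 40 (14 adjusted over the list alone; 0.00589), with lipl-2 at 2.51, lipl-5 at 1.77 and acs-2 at 1.51, an acyl-CoA synthetase induced by fasting. Digestive proteases rose in 17 of 28 (21 higher and 1 lower adjusted over the list alone; 0.0161), with asp-14 at 1.13 and cpr-1 at 1.02. Cuticle collagens as a whole rose in 54 of 170 (70 and 2 adjusted over the list alone; camera adjusted p = 4.4e-14, adjusted p = 0.170 with an estimated correlation), with col-79 and col-73 each at 2.12, and moulting genes in 4 of 18 (5 adjusted over the list alone; 0.354), with qua-1 at 1.75. The moulting score was higher by 4.21 (2.01 within-group standard deviations).

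Other lists called at 4 months did not hold with an estimated correlation. Sperm genes rose in 14 of 57 (20 adjusted over the list alone; adjusted p = 0.170 with an estimated correlation), with nspd-1 at 2.38. Lysozymes and immune effectors rose in 16 of 58 and fell in 2 (18 and 3 adjusted over the list alone; 0.109), with irg-6 at 2.03, and ABC transporters rose in 11 of 48 and fell in 1 (15 and 1 adjusted over the list alone; 0.369), with haf-4 at 0.97. Iron and heme genes rose in 6 of 23 (6 adjusted over the list alone; 0.230), with hrg-11.4 at 1.86, fpn-1.2 at 1.74 and smf-3 at 1.19, and this list had an adjusted p of 0.0705 with a block within each time. Zinc transport rose in 3 of 20 (5 adjusted over the list alone; 0.160), and cdf-2 (0.74), which moves zinc into gut granules, was not called without control array 1 (adjusted p = 0.0633), control array 3 (0.0696) or nZVI array 2 (0.0603). Muscle rose in 5 of 23 (9 adjusted over the list alone; 0.230), with unc-54 at 0.62, DAF-16 targets in 4 of 14 (6 higher and 1 lower adjusted over the list alone; 0.230), with lys-8 at 1.00, yolk proteins in 3 of 5 (4 adjusted over the list alone; 0.170), lipid synthesis in 3 of 23 (8 higher and 1 lower adjusted over the list alone; 0.170) and intestine markers in 2 of 8 (3 adjusted over the list alone; 0.367), with vha-6 at 1.13. The yolk gene vit-6 (1.32) was not called without control array 3 (adjusted p = 0.0631). Without the narrow control arrays 1 and 3 camera's direction for the ABC transporters turned down, with a median of 0.0636 against 0.259 with them.

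Glutathione S-transferases fell at 4 months in 9 of 48 (13 lower and 1 higher adjusted over the list alone; adjusted p = 0.109 with an estimated correlation), with gst-9 and gst-16 (-1.01), and SKN-1 genes in 2 of 13 (4 adjusted over the list alone; 0.109), with gst-4 (-1.04) lost without control array 3 (adjusted p = 0.108) or nZVI array 1 (0.0721), 2 (0.0554) or 3 (0.0565). Heat shock genes fell in 1 of 15 (1 adjusted over the list alone; 0.369), hsp-43 (-0.72), and the list was not called without control array 2 (adjusted p = 0.181), without nZVI array 2 (0.0970) or with the replicate block (0.0547). Metal detoxification was not called (camera adjusted p = 0.986), with 2 of 15 lower, cdr-4 (-0.86) and numr-1 (-1.24), and the numr-1 call was lost without control array 1 (adjusted p = 0.0586) or 3 (0.0790) or nZVI array 2 (0.0559) or 3 (0.0812). cdr-1 was higher at 0.88 ± 0.17 (adjusted p = 0.00515). mtl-2 was at 0.51 ± 0.15 (adjusted p = 0.0536, and 0.0373 with the replicate block), mtl-1 at 0.30 (adjusted p = 0.347) and ftn-1 at -0.13 (adjusted p = 0.785).

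Glycolysis was called higher and ribosomal proteins lower at 4 months without a gene called by limma over all probe sets (6 and 10 at an unadjusted p under 0.05; adjusted p = 0.420 and 0.671 with an estimated correlation), and the glycolysis call was lost without nZVI array 1 (adjusted p = 0.0678). The synapse list was called higher with no gene called by limma (0 at an unadjusted p under 0.05). Its adjusted p was 0.671 with an estimated correlation. The call was lost without control array 1 (adjusted p = 0.541), control array 3 (0.133), nZVI array 1 (0.0678) or nZVI array 2 (0.0673). It was also lost with the replicate block (0.0547). Without both narrow control arrays, which left 1 control array, the median of the list was -0.191 and not 0.257. C-type lectins rose in 31 of 247 and fell in 4 without a list call (camera adjusted p = 0.0863), clec-7 at 2.60. The other lists not called were cytochrome P450 (5 up, 1 down; cyp-37B1 2.18), UDP-glucuronosyltransferases (6, 2), antioxidant enzymes (2, 2), pals (2, 1), antimicrobial peptides (1, 2), embryo (2, 1), respiratory chain (3, 0), histones (0, 2), and hypoxia, osmotic stress, oocyte, vacuolar ATPase and FMRFamide-like neuropeptides (1, 0 each). With the replicate block the antioxidant sod-4, msra-1 and ctl-1 and the antimicrobial abf-6 were not called (adjusted p = 0.0502, 0.0558, 0.0606 and 0.0509). Each was also lost when any of 4 (sod-4, msra-1) or 5 (ctl-1, abf-6) of the 6 arrays was left out. limma called no gene in the endoplasmic reticulum stress, mitochondrial stress, germline, cell division, male and proteasome lists (1, 2, 1, 0, 0 and 3 at an unadjusted p under 0.05).

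The 12 largest rises at 4 months were E01G4.6 (3.56 ± 0.28, 11.8-fold), bli-1 (2.91), F26F2.10 (2.83), pho-11 (2.80 ± 0.14), ZK180.6 (2.79), bli-2 (2.77), cut-4 (2.72), Y51H7C.13 (2.71), col-49 (2.69), rol-1 (2.63), clec-7 (2.60) and znf-782 (2.58). pho-11 encodes an intestinal acid phosphatase and had the smallest adjusted p (5.0e-09). The 12 largest falls were Y53F4B.58 (-2.35), srpr-1.2 (-2.25), lfor-1 (-2.22), ND6 (-2.22), F41H8.5 (-2.16), R151.16 (-2.13), Y51B9A.12 (-2.09), Y23H5B.13 (-2.07), ND4L (-1.96), B0273.111 (-1.77), Y70C5B.2 (-1.72) and K02B9.9 (-1.70), with adjusted p from 0.00416 (K02B9.9) to 0.0454 (srpr-1.2). ND6 and ND4L are subunits of complex I encoded in the mitochondrial genome. Of these 24 genes, 11 were lost without control array 1 (adjusted p 0.0630 to 0.182), 11 without control array 3 (0.0569 to 0.187), 8 without nZVI array 2 (0.0535 to 0.185) and 8 without nZVI array 3 (0.0608 to 0.116). They were 10 of the 12 falls and znf-782.

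**Figure D3:**
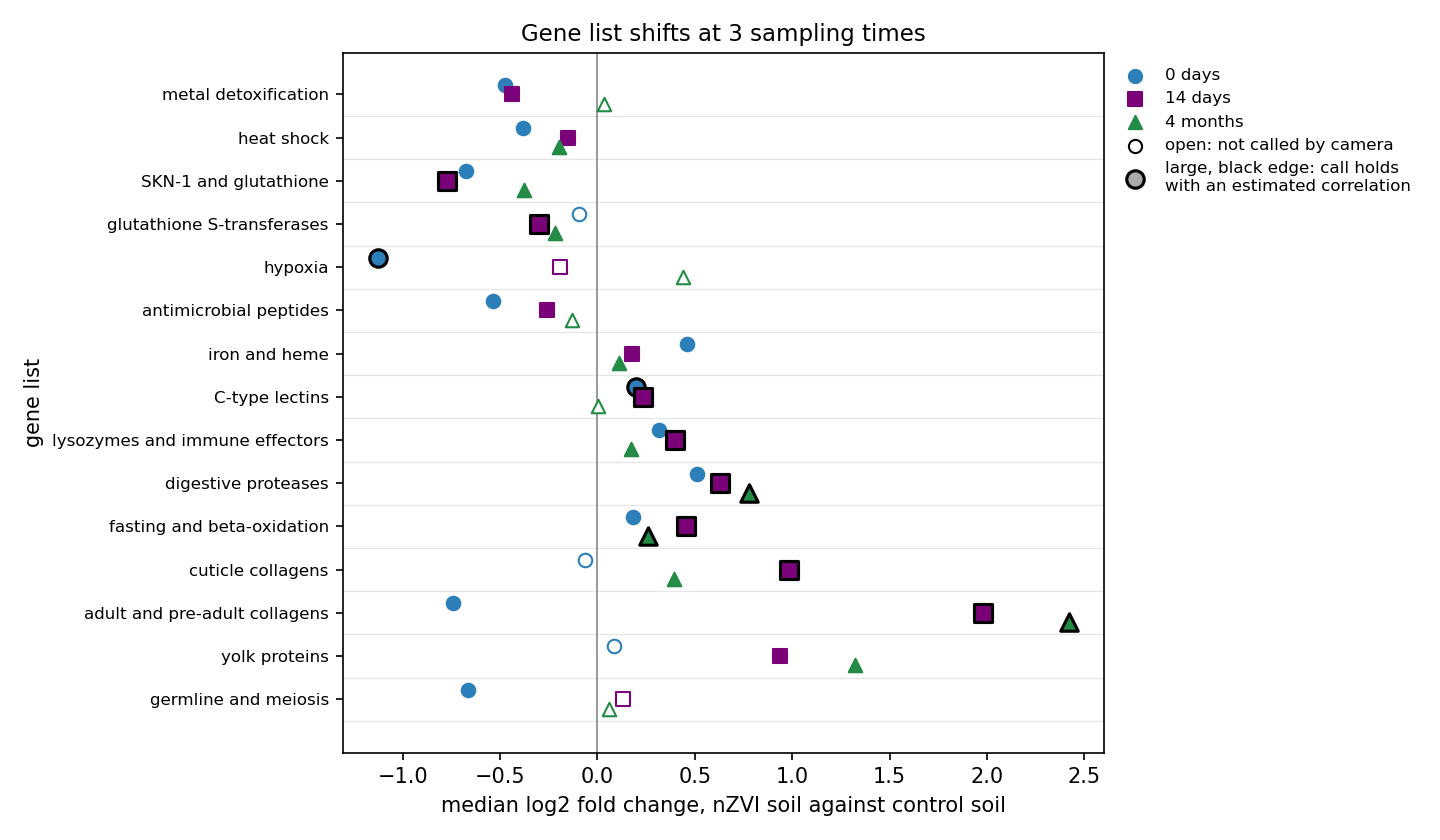
Median log2 fold change of 15 gene lists in nZVI against control soil at 0 days, 14 days and 4 months. Filled points were called by camera, open points were not, and large points with a black edge were also called with an estimated correlation (adult and pre-adult collagens at 14 days 7.1e-04, hypoxia at 0 days 0.00545).

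The fold changes at 0 and 14 days correlated at 0.523 (Pearson), those at 0 days and 4 months at 0.302 and those at 14 days and 4 months at 0.290. With the soil labels swapped within times, 11, 10 and 8 of 100 swaps gave correlations as large in size, so chance was not excluded for them. Swaps that mix the soils keep part of the nZVI effects, so these counts do not decide the question. At 0 and 14 days 1448 probe sets were called at both, 502 up, 903 down and 43 in opposite directions, where independence would give 84.1 up and 118 down. At 0 days and 4 months 710 were called at both (498 up and 157 down, against 111 and 50.6 if independent), and at 14 days and 4 months 609 (442 up and 146 down, against 48.8 and 35.2). Every comparison shared a single estimate of spread per probe set, so calls are not independent and these expected counts may be too low. At all 3 times 284 rose and 127 fell. Those that rose included T22F3.11 (3.31, 2.65 and 2.29), pho-11 (2.46, 1.68 and 2.80), fpn-1.2 (2.10, 2.03 and 1.74) and lipl-5 (1.57, 1.63 and 1.77), and those that fell included parg-2 (-3.33, -3.55 and -1.25) and gst-9 (-3.25, -1.81 and -1.22).

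Averaged over the times, 3117 probe sets rose and 2592 fell (20.1% in total), 394 and 410 of them at least 2-fold (813 at an unadjusted p). Lists that held with an estimated correlation were C-type lectins (84 of 247 up, 2 down; adjusted p = 0.00180), fasting and beta-oxidation (19 of 40 up, 1 down; lipl-1 1.55), digestive proteases (22 of 28 up; cpr-4 1.18, cpr-6 1.12), adult and pre-adult collagens (7 of 8 up), lysozymes and immune effectors (27 of 58 up, 4 down) and SKN-1 and glutathione (8 of 13 down; nit-1 -1.18, gcs-1 -0.96). ftn-1 rose by 1.07 ± 0.14 on average, mtl-2 by 0.50 ± 0.09 (adjusted p = 5.4e-04), vit-2 by 0.58 ± 0.12 (adjusted p = 0.00254), cdr-1 by 0.43 ± 0.10 and ftn-2 by 0.21. mtl-1 and sod-3 were not called (adjusted p = 0.890 and 0.540). The largest average rises were T22F3.11 (2.75), scl-11 (2.69), scl-13 (2.57), scl-12 (2.52), col-108 (2.44) and Y59A8B.26 (2.42), and the largest falls C25F9.2 (-2.96), parg-2 (-2.71), ZC21.10 (-2.48), F43C1.7 (-2.42), F59C12.4 (-2.35) and T05A8.2 (-2.34).

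The nZVI effect on some genes differed between the times. From 0 to 14 days 152 probe sets had a more positive effect and 147 a more negative one (299 in total, 1256 with sample weights and 1189 for a 2-fold change at an unadjusted p). Adult and pre-adult collagens shifted up in 7 of 8 genes (median 2.69, adjusted p = 4.5e-04 with an estimated correlation) and hypoxia genes in 4 of 6 (1.25, 0.0117). Cuticle collagens as a whole shifted up in 50 of 170 (86 higher and 3 lower adjusted over the list alone; adjusted p = 0.0550 with an estimated correlation). The ferritin effect shrank, for ftn-1 by 2.79 (adjusted p = 3.0e-04) and for ftn-2 by 0.72 (adjusted p = 0.0412), while that on cdr-1 turned from a fall to a rise (difference 1.61, adjusted p = 0.00227). The largest shifts up were rol-1 (4.72), col-38 (4.57), E01G4.6 (4.53), col-138 (4.12), col-162 (3.97) and col-133 (3.93), and down Y59A8B.26 (-5.04), fipr-25 (-4.59), cyts-1 (-3.36), F35E8.6 (-3.35), F55H2.8 (-3.31) and cpr-2 (-3.22). The total was 163 without control array 1 and 172 without control array 2 of 0 days, 191, 155 and 189 without control arrays 1, 2 and 3 of 14 days, and 182 without nZVI array 2 of 0 days.

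From 0 days to 4 months 841 probe sets had a more positive effect and 384 a more negative one (1225 in total), 605 and 446 after median centring and 614 and 449 after quantile normalisation. Hypoxia genes shifted up in 5 of 6 (median 1.49, adjusted p = 0.00206 with an estimated correlation) and adult and pre-adult collagens in 5 of 8 (3.43, 0.00206), and C-type lectins down in 9 of 247 and up in 4 (-0.25, 0.0387). ftn-1 shifted by -3.21 (adjusted p = 5.9e-05) and cdr-1 by 1.48 (adjusted p = 0.00228). The largest shifts up were rol-1 (5.32), E01G4.6 (5.00), col-38 (4.48), bli-2 (4.24), C25F9.2 (4.14) and col-138 (4.00), and down scl-11 (-6.37), Y59A8B.26 (-6.23), col-108 (-6.16), spp-11 (-5.48), scl-12 (-5.33) and fipr-25 (-5.002). The total was 2490 with sample weights, 424 without the narrow control arrays 1 and 3 and 1953 for a 2-fold change at an unadjusted p. Left-out arrays gave 736, 805 and 686 (control 1, 2 and 3 of 0 days), 3464 and 660 (control 2 and 3 of 4 months), 680 and 708 (nZVI 2 and 3 of 0 days), and 616 and 759 (nZVI 2 and 3 of 4 months).

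From 14 days to 4 months 333 probe sets had a more positive effect and 54 a more negative one (387 in total), 243 and 82 after median centring. The largest shifts up were C25F9.2 (4.50), K02F3.13 (4.02), T28B11.11 (3.92), T28B11.22 (3.16), T28B11.4 (3.14) and F45H7.8 (3.03), and down col-108 (-3.83), F41H8.5 (-3.33), Y46E12A.5 (-2.61), F47B8.14 (-2.31), K09E2.1 (-2.25) and col-158 (-2.05). T28B11.4 and Y46E12A.5 were not called with the replicate block (adjusted p = 0.0565 and 0.0594). Left-out arrays ended the call of 10 of these 12 genes (adjusted p 0.0506 to 0.121), and every array but control array 2 of 4 months ended at least 1. The total was 172 and 79 without control arrays 1 and 2 of 14 days, 190, 3769 and 101 without control arrays 1, 2 and 3 of 4 months, 97 without nZVI array 1 of 14 days, and 171 and 142 without nZVI arrays 2 and 3 of 4 months. It was 8 without the narrow control arrays 1 and 3, 3818 with sample weights, 181 with only the compared groups in the fit and 1601 for a 2-fold change at an unadjusted p.

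Each time is a separate set of samples, so a change over time cannot be told apart from a difference in culture, worm stage or array run. Mean age scores at 0 days, 14 days and 4 months were -0.69, -6.41 and 9.02 in control soil. In nZVI soil they were -11.6, 0.31 and 9.35. From 0 to 14 days in control soil 1646 probe sets rose and 1726 fell (3372 in total). The total was 8645 with sample weights, 1171 for a 2-fold change and 1409 for that at an unadjusted p. Sperm genes fell in 15 of 57 (17 adjusted over the list alone; adjusted p = 0.584 with an estimated correlation), with nspd-10 at -1.51 and msp-78 at -1.32, and moulting genes rose in 4 of 18 (7 adjusted over the list alone; 0.584), with nhr-25 at 1.69. mtl-1 fell by 0.87 (adjusted p = 0.00701). The largest rises were cyts-1 (2.54), F10A3.4 (2.47), irg-5 (2.32), C12D12.1 (2.31), F35E8.7 (2.24) and F35E8.6 (2.21), and the largest falls C45G9.4 (-3.66), F52H3.10 (-2.86), T16A9.6 (-2.69), W05B2.10 (-2.59), Y53F4B.58 (-2.57) and ZK265.11 (-2.50). F52H3.10 was not called without control array 2 of 0 days (adjusted p = 0.0548), nor Y53F4B.58 without control arrays 1 or 2 of 0 days (0.0905, 0.0580) or of 14 days (0.0703, 0.0618). The total was 1330 and 1226 without control arrays 1 and 2 of 0 days and 1876, 1417 and 2222 without control arrays 1, 2 and 3 of 14 days.

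From 0 days to 4 months in control soil 959 probe sets rose and 1796 fell (2755 in total), 1366 and 1555 after median centring and 1192 and 1417 after quantile normalisation. The total was 745 with only the compared groups in the fit, 766 without the narrow control arrays 1 and 3, 985 for a 2-fold change and 1137 for that at an unadjusted p. FMRFamide-like neuropeptides fell in 23 of 31 (27 adjusted over the list alone; adjusted p = 0.102 with an estimated correlation), with flp-15 at -1.32 and flp-18 at -1.22, and pals genes in 19 of 37 (23 lower and 1 higher adjusted over the list alone; 0.154), with pals-39 at -2.78. mtl-1 fell by 1.49 ± 0.18 (adjusted p = 8.2e-05) and mtl-2 by 0.71 (adjusted p = 0.00724). The largest falls were col-36, grl-20 (-5.06), col-185 (-5.06), col-102 (-4.39), col-44 (-4.31) and ZK218.5 (-4.24), and the largest rises Y45F10C.2 (2.40), Y51B9A.12 (2.33), spp-17 (2.25), clec-174 (2.23), irg-5 (2.10) and Y51H7C.13 (2.00). The total was 1428 and 1620 without control arrays 1 and 2 of 0 days, and 5242 and 1303 without control arrays 2 and 3 of 4 months.

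In nZVI soil adult and pre-adult collagens were higher and ferritin genes lower at both later times than at 0 days. Each time is a separate set of samples, but both comparisons use the same 0-day arrays and are not independent. From 0 to 14 days 1172 probe sets rose and 1326 fell (2498 in total). The total was 3813 with sample weights, 1640 with only the compared groups in the fit, 1056 for a 2-fold change and 1236 for that at an unadjusted p. Adult and pre-adult collagens rose in 7 of 8 (8 adjusted over the list alone; adjusted p = 3.2e-04 with an estimated correlation) and hypoxia genes in 4 of 6 (5 adjusted over the list alone; 0.0187), with sqrd-1 at 1.34. Cuticle collagens rose in 74 of 170 and fell in 4 (93 and 9 adjusted over the list alone; 0.0862), with col-73 at 3.40. ftn-1 fell by 2.92 and ftn-2 by 0.62, and cdr-1 rose by 1.53. The largest rises were irg-6 (4.93), rol-1 (4.83), Y51H7C.13 (4.76), col-38 (4.49), clec-174 (4.37) and bli-2 (4.12), and the largest falls fipr-25 (-3.61), C45G9.4 (-3.61), Y59A8B.26 (-3.16), ftn-1, nta-1 (-2.79) and ZK265.11 (-2.74). The total was 1469 and 1255 without nZVI arrays 1 and 2 of 0 days and 1665 without nZVI array 3 of 14 days.

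From 0 days to 4 months in nZVI soil 3402 probe sets rose and 2896 fell (22.2% in total), the most of any comparison, and 4115 were called without nZVI array 2 of 4 months. A 2-fold change left 2257, and 2334 at an unadjusted p. Germline and meiosis genes rose in 24 of 27 (25 adjusted over the list alone; adjusted p = 0.390 with an estimated correlation), with syp-1 at 1.54 and him-3 at 1.43, and cell division genes in 17 of 31 (22 adjusted over the list alone; 0.390), with cye-1 at 1.02. FMRFamide-like neuropeptides fell in 29 of 31 (30 adjusted over the list alone; 0.0783), with flp-26 at -1.62. Adult and pre-adult collagens rose in 8 of 8 (8 adjusted over the list alone; 0.00102), the call that held with an estimated correlation. ftn-1 fell by 3.69, mtl-1 by 0.86, mtl-2 by 0.59 and ftn-2 by 0.50, and cdr-1 rose by 1.08. The largest rises were rol-1 (5.75), Y51H7C.13 (5.64), col-38 (5.45), E01G4.6 (5.33), col-138 (5.22) and bli-2 (5.09), and the largest falls Y59A8B.26 (-6.93), col-185 (-6.19), scl-11 (-6.12), grl-20 (-5.84), col-108 (-5.76) and spp-11 (-5.29).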

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

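Among the tests of this part, the fits without the narrow control arrays 1 and 3 at 4 months, those with a replicate block within each time, the covariate fits read over all members of the metal detoxification, heat shock and SKN-1 lists, and the swaps with the shared nZVI effect taken out, with and without pairs, were chosen only after the results were seen. The collagen, metal and stress gene, and chemoreceptor patterns weighed below were themselves picked from the results. The results collected here are those whose nZVI effect differed between sampling times by a test of the difference itself, in limma. There were 299 such probe sets between 0 and 14 days, 1225 between 0 days and 4 months, and 387 between 14 days and 4 months. When the soil labels were swapped within times, 7, 5 and 10 of 100 swaps (drawn from 200 each) gave as many or more. This decides nothing, because a swap of the whole label at 1 time adds the nZVI effects that the times share (5048, 4982 and 3402), and a swap that mixes the soils at 1 time alone leaves the effect at the other (up to 4451, 1940 and 972 over mixed swaps). With the mean of the 2 effects first taken from the nZVI arrays, 1, 2 and 1 of 100 swaps gave as many or more, the real one included. The highest other was 3, 1447 and 133. If replicate numbers are taken to pair the soils at 4 months, 80 swaps part all 3 pairs there. Of these, 1 (the real one) reached 1225 and 1 reached 387, with 1 and 7 as the highest other. These added swaps do not exclude chance for the 3 totals. The mean was estimated under the real labels, so a swap of the whole label at 1 time gives no difference by construction. The totals themselves hung on single arrays, 387 falling to 79 without control array 2 of 14 days and to 8 without the narrow control arrays.

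Between 0 and 14 days the effect became more positive for rol-1 (4.72), col-38 (4.57), E01G4.6 (4.53), col-138 (4.12), col-162 (3.97), col-133 (3.93), irg-6 (3.32), clec-174 (2.65), col-19 (2.25), Y105C5B.15 (2.22), col-135 (1.72), cdr-1 (1.61), ZK218.5 (1.53), col-7 (1.49), cysl-2 (1.06) and cye-1 (0.96). It became more negative for Y59A8B.26 (-5.04), fipr-25 (-4.59), cyts-1 (-3.36), F35E8.6 (-3.35), F55H2.8 (-3.31), cpr-2 (-3.22), F35E8.7 (-2.64), gpx-3 (-2.20), abf-6 (-1.47) and ftn-2 (-0.72). The adult and pre-adult collagen list (median 2.69) and the hypoxia list (1.25) shifted up. Many of the genes that shifted up are collagens of the cuticle, and ftn-2 encodes a ferritin subunit.

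Between 0 days and 4 months the effect became more positive for rol-1 (5.32), E01G4.6 (5.00), col-38 (4.48), bli-2 (4.24), C25F9.2 (4.14), col-138 (4.00), col-73 (3.73), bli-1 (3.66), Y51H7C.13 (3.65), srt-42 (3.53), col-49 (3.43), fipr-22 (3.40), sqt-1 (3.39), ZK180.6 (3.14), F26F2.10 (3.13), T05A8.2 (2.88), nlp-29 (2.68), fbxa-75 (2.67), spe-36 (2.59), C33A12.19 (2.58), ZC21.10 (2.52), col-79 (2.50), sqrd-1 (2.45), F17C11.21 (2.38), nspd-1 (2.26), F19B10.13 (2.13), pals-39 (2.10), parg-2 (2.08) and gst-9 (2.04). Smaller shifts up were pgp-6 (1.98), cnc-4 (1.89), F43C1.7 (1.87), F59C12.4 (1.61), syp-3 (1.53), qua-1 (1.52), pals-3 (1.44), irg-5 (1.42), haf-7 (1.28), nit-1 (1.28), acs-2 (1.24), hmt-1 (1.12), smf-3 (1.10), fasn-1 (1.08), cyp-37B1 (1.05), asp-14 (0.97), cdf-2 (0.92), gcs-1 (0.78), hsp-43 (0.77) and rpn-3 (0.67). Several of these, among them nit-1, gcs-1, hmt-1 and hsp-43, were lower in nZVI soil at 0 days. The effect became more negative for scl-11 (-6.37), Y59A8B.26 (-6.23), col-108 (-6.16), spp-11 (-5.48), scl-12 (-5.33), fipr-25 (-5.002), scl-13 (-4.87), T26C12.2 (-4.80), oac-39 (-4.62), tyr-3 (-4.53), F47B8.13 (-4.38), T05B4.12 (-4.25), ftn-1 (-3.21), cyp-34A2 (-2.71), smf-2 (-2.55), nta-1 (-2.23), lipl-3 (-1.66), pgp-14 (-1.49), tnt-4 (-1.28), pyk-2 (-1.20), lipl-1 (-1.18) and clec-31 (-1.06). The hypoxia list (1.49) and the adult and pre-adult collagen list (3.43) shifted up and the C-type lectins (-0.25) down.

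Between 14 days and 4 months the effect became more positive for C25F9.2 (4.50), K02F3.13 (4.02), T28B11.11 (3.92), T28B11.22 (3.16), T28B11.4 (3.14), F45H7.8 (3.03), Y42A5A.11 (3.02), C14F11.11 (3.01), T04C12.23 (3.00), R11D1.14 (2.75), fbxa-50 (2.07), clec-7 (1.99), irg-2 (1.65), pho-11 (1.13) and cdr-4 (0.78). It became more negative for col-108 (-3.83), F41H8.5 (-3.33), Y46E12A.5 (-2.61), F47B8.14 (-2.31), K09E2.1 (-2.25), col-158 (-2.05) and clec-66 (-1.22).

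The higher cuticle collagens were weighed at both later times (170 genes, median log2 fold change 0.98 at 14 days and 0.40 at 4 months). With the age score in the fit the medians were 1.12 (1.07 to 1.15 when single arrays were left out) and 0.39 (0.26 to 0.48), and with each array's interquartile range 0.95 (0.81 to 1.11) and 0.54 (0.42 to 0.83). At 14 days the age values argue against developmental age, as the genes of that score read it, as the whole cause. The soil difference in the age score fell there from 6.72 to 1.89 without nZVI array 2. At 4 months the interquartile range values argue against narrow arrays as the whole cause. The age score at 4 months and the interquartile range at 14 days differed between the soils by only 0.073 and -0.44 within-group standard deviations. Those fits had little to remove and decide nothing. With the moulting score the median was 0.85 (0.75 to 1.28) at 14 days and 0.27 (0.14 to 0.43) at 4 months. At 14 days this argues only against the phase of the moult as that score reads it, as the whole cause over all 170 genes. The soil difference in that score hung on single arrays there, and the adult and pre-adult collagens were not read by themselves. At 4 months moult and soil cannot be told apart, because the range reaches below 50% of the median without the score. An effect of nZVI on the cuticle and whether each soil held a separate culture of worms both stay open.

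The lower metal detoxification, heat shock and SKN-1 genes at 0 and 14 days were weighed as a set (36 calls, median -1.25). With the age score in the fit the median was -1.37 (-1.31 to -1.48), and with the interquartile range -1.25 (-1.24 to -1.34). These calls were picked for their fall, so all members of the 3 lists at both times were read as well (86 values, median -0.48), giving -0.44 (-0.42 to -0.48) and -0.49 (-0.45 to -0.53). These values do not decide whether age as that score reads it, or array spread, was the whole cause. The age score differed (nZVI minus control) by -10.9 at 0 days and 6.72 at 14 days. Its adjustments could therefore cancel in a median over both times. The interquartile range differed by only -0.35 and -0.44 within-group standard deviations at these times, so that fit had little to remove. The moulting score was higher in nZVI soil by 2.21 within-group standard deviations at 0 days and was not weighed for these genes. What lowered these genes stays open, and metal levels in the soils or worms were not used here. Some metal detoxification genes rose, mtl-2 at 14 days (0.59) and on average (0.50) and cdr-1 at 14 days (1.01) and 4 months (0.88).

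Camera called chemoreceptor classes lower in nZVI soil at 4 months in 12 of 21 classes (1040 genes, median -0.14), but none with an estimated correlation. Of the genes limma called 6. Random sets of 1040 other genes of the same signal level had a median of -0.13 (-0.15 to -0.12 over 1000 sets), and without the narrow control arrays 1 and 3 the chemoreceptor median was -0.0076. A shift of dim probe sets on these arrays may therefore account for it. The median over these genes of their mean log2 signal was 2.50, and across the range of signal the lowest 25% of probe sets shifted by -0.14 and the third 25% by 0.17.

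Other splits of the same samples were counted for the remaining results. Each comparison of 3 against 3 arrays has 10 splits, too few for a share under 0.05. The real split and the highest other called 4530 and 0 probe sets at 0 days, 2552 and 13 at 14 days, 3372 and 0 (14 days) and 2755 and 149 (4 months) against 0 days in control soil, and 2498 and 101 and then 6298 and 1 in nZVI soil. In each, 1 of 10 splits, the real one, reached the real value. At 4 months replicate numbers were taken to pair the soils. There the real split called 2009 and the 3 others that part all 3 pairs called 0, while 426 came from a split that parts 1 pair. Gene lists called were 26 against 16, 24 against 22 and 21 against 14 (1 of 10 each), and gene classes 70 against 53, 38 against 61 and 48 against 64, so that 1, 5 and 4 of 10 splits reached the real number of classes. For the average over times, 1 of 100 label swaps (drawn from 4000) reached 5709, the real one, and the highest other gave 1327. That excludes chance only as spread between these arrays. Swaps of arrays cannot exclude a chance difference between the cultures in each soil. For the correlations of the effects, 11, 10 and 8 of 100 swaps gave sizes as large as 0.523, 0.302 and 0.290 (highest 0.617, 0.429 and 0.355). Chance was not excluded, but swaps that mix the soils keep part of the nZVI effects, so this does not decide the question.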

How the results depend on the processing

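The fits without the narrow control arrays 1 and 3 at 4 months and the replicate block within each time were chosen after the data were seen. Where no reason is given, the cause was not tested. The number of probe sets called stayed within 1.5 times under quantile normalisation, cyclic loess, median centring, both filters on dim probe sets, the robust variance model, probe sets with 1 gene name and the replicate block. With only the compared groups in the fit there were 382 at 4 months, 181 for the difference of the effect between 14 days and 4 months, 745 for 4 months against 0 days in control soil and 1640 for 14 days against 0 days in nZVI soil. For the average over times this setting is the fit itself, so there is no value.

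Sample weights raised the calls to 6846 at 14 days, 3394 at 4 months, 8645 and 3813 for 14 days against 0 days in control and nZVI soil, and 1256, 2490 and 3818 for the 3 differences between times. Without the narrow arrays, which left a single control array at 4 months assumed to vary like the other groups, 186 were called at 4 months, 766 for 4 months against 0 days in control soil, and 424 and 8 for the differences of 4 months from 0 and from 14 days. A fold threshold of 2 beside the adjusted p left 1727, 1210, 936 and 804 for the nZVI comparisons at 0 days, 14 days, 4 months and on average, 1171 and 985 in control soil and 1056 and 2257 in nZVI soil over time. Beside an unadjusted p it gave 1827, 1332, 1292 and 813, then 1409 and 1137, 1236 and 2334, and 1189, 1953 and 1601 for the differences between times.

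Leaving out single arrays gave 2826 to 4196 calls at 0 days, 1562 to 2814 at 14 days, 773 to 5415 at 4 months and 4784 to 6907 on average. The differences between times gave 155 to 368, 616 to 3464 and 79 to 3769. The comparisons over time gave 1226 to 3222 and 1303 to 5242 in control soil and 1255 to 2388 and 4115 to 5565 in nZVI soil. The arrays behind each shift over 1.5 times are named with each comparison.

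Of 126 list tests at single times 71 were called (68 to 75 without single arrays), and of 519 class tests 156 (142 to 171). With an estimated correlation 13 lists and 2 classes were called, the classes being the C-type lectins at 0 and 14 days. Of the 71 list calls, fry did not call 15, single left-out arrays ended 12, leaving out the lowest 25% of probe sets ended 8, cyclic loess 4, quantile normalisation 1 and median centring none, the replicate block 2 and the block within each time 1. The mean of probe sets per gene ended none. All 71 kept their direction under quantile normalisation, median centring and cyclic loess. Leaving out dim probe sets ended heat shock at 0 and 14 days (adjusted p = 0.101 and 0.0699), sperm (0.0548) and adult and pre-adult collagens (0.0510) at 0 days, and iron (0.0562), DAF-16 (0.0542), glycolysis (0.110) and synapse (0.187) at 4 months. Quantile normalisation ended synapse at 4 months (0.0608). Cyclic loess ended zinc and iron (0.0539 each), glycolysis (0.0979) and synapse (0.124) at 4 months. The blocks ended heat shock and synapse (0.0547 each) and iron (0.0705) at 4 months. No other list call changed under a block.

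Without the narrow control arrays the list calls at 4 months of zinc (adjusted p = 0.138), iron (0.0571), glycolysis (0.0700), ribosomal proteins (0.301) and intestine (0.345) were lost, and 2 reversed, ABC transporters (camera direction down, median 0.0636, adjusted p = 0.399) and synapse (median -0.191, adjusted p = 0.0332). Of 174 calls of named genes, 26 were lost when a single array was left out, 5 under cyclic loess, 2 under quantile normalisation and 2 under the replicate block, and none changed direction. Among them srpr-1.2 at 4 months had an adjusted p of 0.0511 under loess, and in the difference between 14 days and 4 months col-108 had 0.0508 under loess and K09E2.1 0.0629 and 0.0648 under quantile and loess. Of 945 calls of leading list members, 278 were lost when a single array was left out, 24 under loess, 25 under median centring, 29 under quantile normalisation and 17 under the block. Genes not called came to be called in some settings: mtl-2 at 0 days (quantile, 0.0466) and 4 months (quantile 0.0148, loess 0.0465, block 0.0373), and vit-2 at 14 days (quantile 0.0246, loess 0.0389, median centring 0.0387) and 4 months (quantile 0.0390). The effect correlations between times ran from 0.426 to 0.636, 0.257 to 0.358 and 0.180 to 0.364 without single arrays.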

Other observations

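Camera called gene families outside the lists, although at 14 days and 4 months 5 and 4 of 10 splits of the same arrays called as many classes or more (38 and 48 called, highest other 61 and 64). The nspg genes, which encode small secreted peptides, rose in nZVI soil in 9 of 14 at 0 days, 8 at 14 days and 8 at 4 months (camera adjusted p = 5.1e-05, 1.2e-07 and 6.5e-06), and the abu genes in 7 of 14 at 14 days and 6 at 4 months. With an estimated correlation these had adjusted p of 0.278, 0.136 and 0.345 for nspg and 0.375 and 0.470 for abu. At 0 days neuropeptide receptors (npr) rose in 11 of 44 genes and ligand-gated channels (lgc) in 13 of 55, with 1 lower, while mitochondrial ribosomal proteins (mrpl) fell in 6 of 41, vps genes of vesicle sorting in 9 of 34 and translation initiation factors (eif) in 6 of 23. At 14 days nuclear hormone receptors (nhr) fell in 32 of 271 with 1 higher and F-box genes (fbxa) in 22 of 188. None of these classes was called with an estimated correlation.

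With a covariate in the fit the number of probe sets called between the soils changed. With the age score it was 2616 at 14 days and 2312 at 4 months, with the moulting score 3317 at 14 days, and with the interquartile range 4928 at 0 days and 2644 at 14 days. The interquartile range differed between the soils by 0.28 at 4 months, 2.78 times its within-group standard deviation. nZVI array 2 at 14 days, which lay apart on the first principal component, had a moulting score of -2.21 against 4.83 and 5.52.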
